A study of Homo sapiens with 18 samples.

How the data were processed

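RNA was measured on 18 Affymetrix Human Gene 2.0 ST arrays, 3 per group in 6 groups. Per the labels, SKBR3 cells were given a control antisense oligonucleotide (ASO) or an ASO against the long non-coding RNA LINC01269, and MDA-MB-231 and MDA-MB-468 cells were given a control ASO or an ASO against the long non-coding RNA AL078604.2. The ASOs were GapmeRs at 15 nM for 48 h, delivered with TransIT-BrCa, per the labels' protocols. RNA was collected in TRIzol, purified with a PureLink kit and labelled with the WT PLUS kit, also per the labels' protocols.

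The array scans were processed by the authors in Transcriptome Analysis Console, per the submitters' processing notes and the series' design text. Its version, the summarization and normalization method and the genome build were not given in the sources used here. The deposited values run from 0.41 to 13.84 and were read as log2 expression per transcript cluster, here called a feature, from their range and spread, since neither the labels nor the table's header names a scale. Array medians were 4.56 to 4.63 in the SKBR3 group of arrays, 5.41 to 5.43 in the MDA-MB-231 group and 5.21 to 5.24 in the MDA-MB-468 group, so the lines appear to have been scaled separately, and levels were not compared between lines except on a percentile or quantile-normalized scale. An array gives no count of molecules, so the number of arrays limits the precision.

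The table held 53617 features. GEO's platform annotation gave 1 gene symbol to 16098 of them (14884 distinct symbols), several to 0 and none to 37519, which are unnamed here, not without a gene. Symbols were updated, and gene span lengths taken, from a RefSeq table of the GRCh38.p14 assembly. Gene neighbours were found from the chromosome and start position in the same RefSeq table. Neither LINC01269 nor AL078604.2 had a named feature, so the level of the targeted RNAs was not analysed here. Control probes were not marked in the files and were therefore not removed, although the design planned to remove them.

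Tests were run in R 4.3.3 with limma 3.58.1. A feature was tested when its mean exceeded the group's median of all features in at least 1 of the 6 groups, which left 29855 features, 12003 of them with a symbol (11149 distinct). A group-means model was fitted to all 18 arrays with 12 residual degrees of freedom, and limma's moderated test with an intensity trend was used (4.33 prior degrees of freedom). P-values were two-sided and adjusted by Benjamini-Hochberg over the features of a comparison, with a threshold of 0.05. The comparisons were each anti-lncRNA ASO against the control ASO of its line, and the difference between both lines given the anti-AL078604.2 ASO. These comparisons, the filter, the gene lists, the rule for named genes and, but for those said to be added, the alternatives were chosen before the data were examined. The mean of both anti-AL078604.2 comparisons was added after the data had been seen.

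Genes were named by rule. Among features with 1 symbol that passed and whose 3 anti-lncRNA arrays lay beyond all 3 control arrays, the 10 largest rises and 10 largest falls were taken. Where none passed, the 5 smallest p-values in each direction were given as not passing. For each list described, up to 4 members with the smallest p were named, and for the difference between lines up to 5 genes per direction. Genes called in both lines and a fixed set of cell line markers were also named. Genes set beside these for comparison between lines, members of marker lists, the unnamed feature called in the MDA-MB-468 arrays, neighbouring pairs and the genes that differed most between lines were chosen after their values were seen.

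Of 32 gene lists fixed in advance, 28 had at least 5 tested members. Replication-dependent histones and mitochondrially encoded transcripts had 0 named features, and leukocyte markers and fibroblast and endothelial markers had 4 tested members each, so these lists were not tested. Lists were tested with camera at a preset correlation of 0.01, with 1 feature per gene and adjustment over the lists of a comparison, and again with an estimated correlation and with fry. List means per array were also compared by an exact two-sided permutation of arrays within each line, an alternative added after the data had been seen.

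The procedure was tested on simulated data with 29855 genes and 200 changed genes per line. In the simulated SKBR3 comparison it recovered 37 of 67 genes changed 1.5-fold, 59 of 67 changed 2-fold and 64 of 66 changed 3-fold, with 10 other calls. In the simulated MDA-MB-231 comparison it recovered 44, 59 and 64, with 8 other calls, and in the simulated MDA-MB-468 comparison 38, 62 and 66, with 9 other calls. A list raised in each simulated comparison was called, with 0 other lists. The simulated arrays and genes varied independently of each other, so the list simulation did not test lists whose genes vary together. The simulated rise of the list was larger than the median change of most lists called below.

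Alternatives covered no filter and a stricter filter, quantile normalization, centring each array on its median, fitting only the arrays of a comparison, a robust fit without trend, array weights, the replicate number as a block, 1 feature per gene symbol, 2-fold thresholds and leaving out each array in turn. Removal of a gene length trend was added after the data had been seen. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.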

Results

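The arrays measured RNA in cells labelled as 3 breast cancer lines after 48 h with an antisense oligonucleotide that directs cleavage of its target RNA. SKBR3 is a HER2-positive line, and MDA-MB-231 and MDA-MB-468 are triple-negative lines. The design asks how loss of LINC01269 alters gene expression in the first line and how loss of AL078604.2 alters it in the others. Each of the 6 groups had 3 arrays. Correlations between replicate arrays ran from 0.978 to 0.985 in the arrays labelled SKBR3, from 0.985 to 0.991 in those labelled MDA-MB-231 and from 0.980 to 0.991 in those labelled MDA-MB-468. No pair of arrays held identical values. The knockdown of either target was not analysed here, because neither long non-coding RNA has a named feature.

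Marker genes of the control arrays ran partly against and partly with the line labels. Against them, the epithelial adhesion molecule EPCAM stood at the 98.9 percentile of all features in the arrays labelled SKBR3, at 99.2 in those labelled MDA-MB-231 and at 99.3 in those labelled MDA-MB-468, although MDA-MB-231 is known as a mesenchymal-like line low in EPCAM. The 22 named epithelial genes had median percentiles of 95.8, 95.2 and 94.5 in the same order. Among other epithelial genes, CLDN7 stood at 96.3, 96.9 and 97.3, and ESRP1 at 98.1, 98.1 and 98.0. The intermediate filament gene VIM, abundant in MDA-MB-231, stood at 76.3, 76.7 and 82.4. GRB7, which is co-amplified with ERBB2 in SKBR3, stood at 79.2, 81.3 and 78.9. ERBB2 and CDH1 have no named feature here. On a quantile-normalized scale, the 12 named genes of the ERBB2 amplicon had a median difference of 0.04 log2 between the arrays labelled SKBR3 and the other lines, and the highest was ORMDL3 with 0.50. The epidermal growth factor receptor gene EGFR, known to be amplified in MDA-MB-468, was highest in the arrays labelled SKBR3 (0.42) and differed by 0.02 in those labelled MDA-MB-468 (percentiles 99.0, 98.2 and 98.7). The 13 named mesenchymal genes had a median difference of -0.16 in the arrays labelled MDA-MB-231, with AXL the highest at 1.09. With the labels, the luminal keratin KRT18 was highest in the arrays labelled SKBR3 (0.57 against the other lines, percentiles 98.7, 98.5 and 97.0). Its order in the other lines ran against them, with 0.31 in those labelled MDA-MB-231 and -0.88 in those labelled MDA-MB-468. Also with the labels, the basal keratin KRT5 was highest in those labelled MDA-MB-468 (1.47, percentiles 69.8, 73.6 and 85.8). But the basal keratin KRT14 was highest in those labelled MDA-MB-231 (1.60). The basal list had medians of 0.10 in those labelled MDA-MB-468 and 0.13 in those labelled MDA-MB-231. In the arrays labelled MDA-MB-468, the tumour suppressor gene RB1 (-1.60), the receptor kinase gene AXL (-1.76) and the mesenchymal repressor gene ZEB1 (-0.61) were lowest. RB1 (1.30) and ZEB1 (0.39) were highest in those labelled MDA-MB-231, although ZEB1 stood low in each line (percentiles 43.8, 45.9 and 33.3). The luminal and HER2-enriched list was highest (median 0.30) and the basal list lowest (-0.36) in those labelled SKBR3. The oestrogen receptor gene ESR1 stood at percentiles 60.1, 55.7 and 52.7. These are values without a test. Control means of the 3 labelled lines were also much alike, with r from 0.971 to 0.980 between lines. Only 14 to 54 of 29855 features differed at least 4-fold between 2 lines. Because the markers did not settle the labels, every direction below is one between arrays labelled with a line and a treatment.

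**Figure D1:**
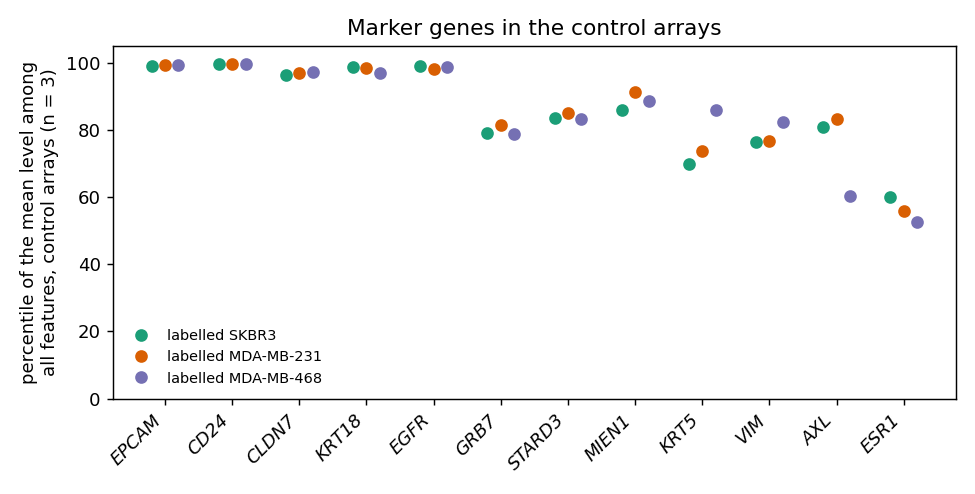
Percentile of the mean log2 level of each marker gene (horizontal axis) among all features of the control arrays (vertical axis, percent), with 1 point per labelled line (mean of n = 3 arrays, no error bars). EPCAM lies between 98.9 and 99.3 in all 3 labelled lines, and VIM between 76.3 and 82.4.

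In the arrays labelled SKBR3, no single gene passed the test after the anti-LINC01269 ASO. The genes with the smallest p that were higher were TRIM61 (0.73 ± 0.12 log2, SE, n = 3 per group), the microRNA gene MIR4481 (0.51 ± 0.0976) and the melatonin receptor gene MTNR1B (0.73 ± 0.142), each with adjusted p = 0.239. HSPA7, a heat shock protein pseudogene (0.71), and MIR486-1 (0.51) had adjusted p = 0.313. Among lower values were those of RTKN2 (-1.59 ± 0.315, adjusted p = 0.239), the claudin gene CLDN16 (-0.75), GLYATL2 (-0.23), EVI5, a regulator of cell division (-1.18 ± 0.276), and the skin barrier gene LCE6A (-0.44), the last 4 with adjusted p = 0.313. limma called 0 of 29855 features, while 2736 had an unadjusted p under 0.05, of which 1604 were higher. Groups did not overlap for 11.6% of features, where chance gives 10%. Leaving out anti-LINC01269 replicate 2 gave 231 calls, leaving out control replicate 2 gave 5 and leaving out anti-LINC01269 replicate 3 gave 1.

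Immediate early and MAPK feedback genes, the fast transcriptional targets of growth factor signalling, rose as a list in the arrays labelled SKBR3 by a median of 0.18 log2 and a mean of 0.19 over 27 genes, 23 of them above 0 (camera adjusted p = 0.000448). With an estimated correlation the adjusted p was 0.713. No member passed over all genes, and 0 passed when adjusted over the list alone. The leading members, none passing, were FOSL1 (0.71), MYC (0.44), ETV5 (0.47) and EGR1 (0.31), all transcription factors. Mesenchymal genes rose by a median of 0.16 over 10 genes (adjusted p = 0.0271, and adjusted p = 0.713 with an estimated correlation), with 0 members passing over all genes and 1, the repressor ZEB2 (0.54), when adjusted over the list alone. Glycolysis and hypoxia genes rose by a median of 0.14 over 18 genes (adjusted p = 0.0359, and adjusted p = 0.713 with an estimated correlation), with 0 members passing either way. The glycolysis call was lost without control replicate 1 (adjusted p = 0.119), control replicate 3 (0.282) or anti-LINC01269 replicate 2 (0.88). The mesenchymal call was lost without control replicate 2 (0.0874), anti-LINC01269 replicate 1 (0.0518) or anti-LINC01269 replicate 2 (0.192).

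In the arrays labelled MDA-MB-231, TFPI2, a secreted inhibitor of serine proteases, rose 6.89-fold after the anti-AL078604.2 ASO (2.78 ± 0.362 log2, SE, n = 3 per group, limma adjusted p = 0.0164). The cytokine receptor gene IL7R (1.47 ± 0.284, adjusted p = 0.0498), the MAPK phosphatase gene DUSP1 (1.15 ± 0.183, 0.0208), the endothelin precursor gene EDN1 (1.14 ± 0.187, 0.0208) and the carboxypeptidase gene CPA4 (0.99 ± 0.175, 0.032) also rose. So did the microRNA gene MIR21 (0.85), the transcription factor genes EGR1 (0.83) and JUN (0.78), FOXD2-AS1 (0.68) and CMTM3, a MARVEL-domain membrane protein gene (0.66 ± 0.104, 0.0208). The nuclear import receptor gene IPO9 fell most among named genes (-1.11 ± 0.204, 0.04), followed by WDR4, a subunit of a tRNA methyltransferase (-0.93 ± 0.174, 0.0422), and the secreted protease gene HTRA1 (-0.85 ± 0.146, 0.0277). Smaller falls were those of EPS15L1, which acts in endocytosis (-0.63), the receptor kinase-like gene ROR1 (-0.61), the Notch coactivator gene MAML3 (-0.50), the ubiquitin ligase gene RNF115 (-0.49), LIX1L (-0.46) and WSB2 (-0.33).

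limma called 51 of 29855 features in the arrays labelled MDA-MB-231, 29 higher and 22 lower. Of these, 26 had a symbol (17 higher and 9 lower) and 25 were unnamed here. All 51 had no overlap between groups, as did 17.2% of all features, where chance gives 10%. Without control replicate 1, 2 or 3, or anti-AL078604.2 replicate 2 or 3, the count was 0, and without anti-AL078604.2 replicate 1 it was 532. All the genes named in this comparison lost their call in the same 5 omissions, with TFPI2 reaching an adjusted p of up to 0.107 and IL7R up to 0.361.

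**Figure D2:**
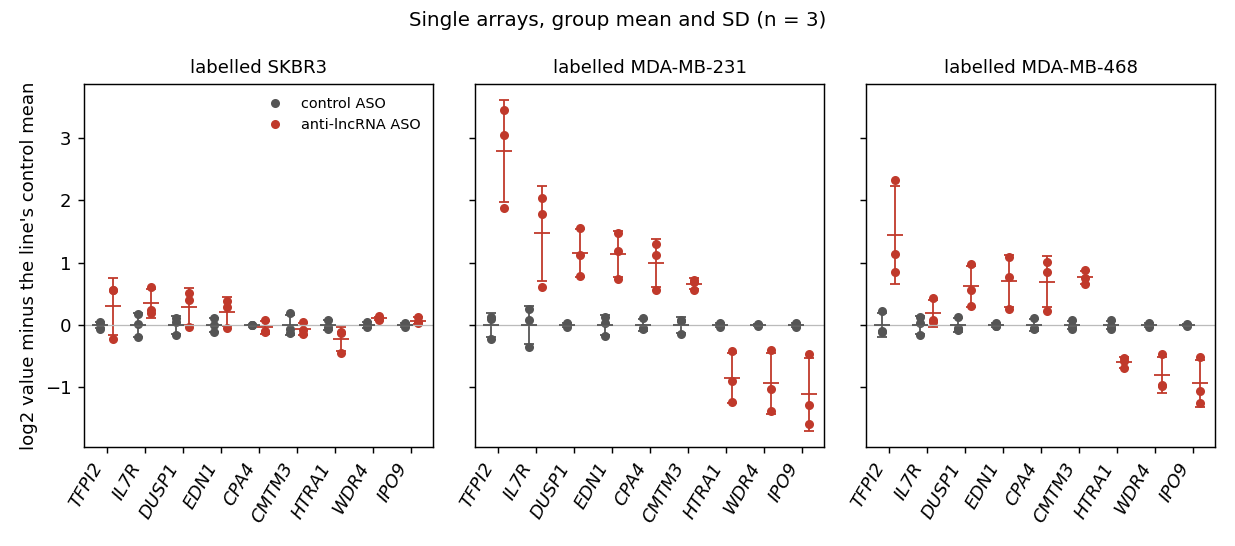
Single arrays (points), group means (horizontal bars) and SD (error bars, n = 3) of 9 genes in each labelled line, as the log2 value minus the mean of that line's control arrays (vertical axis), with control ASO in grey and anti-lncRNA ASO in red. TFPI2 was 2.78 higher in the arrays labelled MDA-MB-231, where it passed the test, and 1.44 higher in those labelled MDA-MB-468, where it did not.

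Immediate early and MAPK feedback genes rose in the arrays labelled MDA-MB-231 by a median of 0.38 and a mean of 0.35 log2 over 27 genes, 25 of them above 0 (camera adjusted p = 1.6e-11). The adjusted p was 0.184 with an estimated correlation. Over all genes 3 members passed (DUSP1, JUN and EGR1), and 14 passed when adjusted over the list alone. Interferon-stimulated genes rose by a median of 0.19 over 24 genes (adjusted p = 2.57e-05, and adjusted p = 0.0947 with an estimated correlation), with 0 members passing over all genes and 8 when adjusted over the list alone. Their leading members were the antiviral genes IFIT2 (0.94) and IFIT3 (0.66), the transcription factor gene IRF7 (0.38) and IFITM1 (0.26). Nucleic acid sensing genes rose by a median of 0.12 over 14 genes (adjusted p = 0.0172, and adjusted p = 0.0947 with an estimated correlation), with 0 and 2 passing in the same order, led by the adaptor gene TICAM1 (0.40) and the DNA sensor gene CGAS (0.62). NF-kB inflammatory genes rose by a median of 0.17 and a mean of 0.35 over 11 genes (adjusted p = 0.000856, and adjusted p = 0.184 with an estimated correlation), with 0 and 2 passing, led by the chemokine genes CCL2 (1.42) and CCL20 (0.91). TGF-beta targets rose by a median of 0.09 over 11 genes (adjusted p = 0.016, and adjusted p = 0.0947 with an estimated correlation), with 1 passing over all genes, the inhibitory gene SMAD6 (0.45), and 2 when adjusted over the list alone. None of these 5 lists lost its call without any 1 of the 6 arrays.

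Cholesterol and fatty acid synthesis genes fell in the arrays labelled MDA-MB-231 by a median of -0.10 over 25 genes, 22 of them below 0 (camera adjusted p = 0.00135, and adjusted p = 0.333 with an estimated correlation). Their leading members were the mevalonate pathway gene MVD (-0.59) and ACACA, which makes malonyl-CoA (-0.27), with 0 passing over all genes and 0 when adjusted over the list alone. Basal epithelial genes fell by a median of -0.11 over 9 genes (adjusted p = 0.0351, and adjusted p = 0.333 with an estimated correlation), with 0 passing either way. DNA replication and G1/S genes rose by a median of 0.11 over 25 genes (0.0223, and adjusted p = 0.516 with an estimated correlation), with 0 passing either way. Lysosome and autophagy genes rose by 0.11 over 23 genes (0.0252, and adjusted p = 0.279 with an estimated correlation), with 0 passing over all genes and 3 when adjusted over the list alone, led by the autophagosome gene MAP1LC3B (0.49). YAP and TEAD targets rose by 0.16 over 12 genes (0.0252, and adjusted p = 0.333 with an estimated correlation) with 0 and 1 passing in the same order, led by AJUBA (0.44). Apoptosis regulators rose by 0.12 over 19 genes (0.0252, and adjusted p = 0.184 with an estimated correlation) with 0 and 1 passing, led by the pro-apoptotic gene PMAIP1 (0.66).

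Some of these calls in the arrays labelled MDA-MB-231 depended on 1 array. Without control replicate 1, the adjusted p was 0.0525 for DNA replication, 0.0974 for apoptosis regulators, 0.0528 for YAP and TEAD targets and 0.0545 for lysosome and autophagy. Without anti-AL078604.2 replicate 1 it was 0.0745 for DNA replication, 0.0749 for YAP and TEAD targets and 0.0745 for lysosome and autophagy, and without control replicate 3 it was 0.0858 for YAP and TEAD targets. Basal epithelial genes lost the call without control replicate 2 (0.0709), control replicate 3 (0.137), anti-AL078604.2 replicate 2 (0.0871) or anti-AL078604.2 replicate 3 (0.138). The cholesterol list kept its call in each of the 6 omissions.

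In the arrays labelled MDA-MB-468, CMTM3 rose 1.70-fold after the anti-AL078604.2 ASO (0.76 ± 0.104 log2, SE, n = 3 per group, limma adjusted p = 0.0213). It and 1 unnamed feature (17020846, 0.51 ± 0.0684, adjusted p = 0.0213) were the 2 calls, both higher, while 3131 features had an unadjusted p under 0.05. Lower values that did not pass were those of WSB2 (-0.32, adjusted p = 0.0817), the MYC-interacting gene CDCA7L (-0.70, 0.12), RNF115 (-0.45, 0.12), DENND11 (-0.58, 0.123) and FOXRED2 (-0.42, 0.129). TFPI2 (1.44, 0.205), EDN1 (0.70, 0.235), DUSP1 (0.62, 0.272) and IPO9 (-0.94, 0.16) did not pass either. Groups did not overlap for 16.9% of features, where chance gives 10%. The count of calls was 12 without anti-AL078604.2 replicate 3, 1 without control replicate 1 and 0 without any other array of this comparison (control replicates 2 and 3, anti-AL078604.2 replicates 1 and 2). CMTM3 lost its call in each omission but that of anti-AL078604.2 replicate 3, with an adjusted p of up to 0.237.

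Immediate early and MAPK feedback genes rose in the arrays labelled MDA-MB-468 by a median of 0.19 and a mean of 0.21 log2 over 27 genes, 24 of them above 0 (camera adjusted p = 0.000228, and adjusted p = 0.624 with an estimated correlation). None passed over all genes and 1, the transcription factor gene ETV1 (0.57), passed when adjusted over the list alone. The other 6 lists called had an adjusted p of 0.0336. Interferon-stimulated genes rose by a median of 0.07 over 24 genes (adjusted p = 0.491 with an estimated correlation), led by the ISG15 ligase gene HERC5 (0.65), and glycolysis and hypoxia genes by 0.14 over 18 genes (adjusted p = 0.721 with an estimated correlation), led by the mitophagy gene BNIP3 (0.50), with 0 members of either list passing over all genes or when adjusted over the list alone. Basal epithelial genes fell by a median of -0.11 over 9 genes (adjusted p = 0.491 with an estimated correlation), with KRT5 (-0.45) the 1 member passing when adjusted over the list alone. Stem cell and ALDH genes fell by -0.06 over 13 genes (adjusted p = 0.491 with an estimated correlation), with 3 passing on that count, the adhesion receptor gene CD44 (-0.33), the pluripotency factor gene SOX2 (-0.37) and the aldehyde dehydrogenase gene ALDH2 (-0.54). NRF2 targets fell by -0.11 over 10 genes (adjusted p = 0.533 with an estimated correlation), with 3 passing on that count, TKT (-0.42), the glutathione reductase gene GSR (-0.28) and PGD (-0.23). DNA replication and G1/S genes fell by -0.07 over 25 genes (adjusted p = 0.721 with an estimated correlation), with CDC45, part of the replicative helicase (-0.33), the 1 member passing when adjusted over the list alone. No member of these 4 falling lists passed over all genes.

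All 7 list calls in the arrays labelled MDA-MB-468 were lost in some omission of 1 array. Without anti-AL078604.2 replicate 1 the adjusted p was 0.404 for immediate early genes, 0.223 for interferon-stimulated genes and 0.473 for glycolysis. Without control replicate 1 it was 0.172 for interferon-stimulated genes, 0.145 for DNA replication, 0.536 for glycolysis, and 0.064 for both basal and stem cell genes. Without control replicate 2 it was 0.0934 for interferon-stimulated genes, 0.0948 for DNA replication, 0.094 for glycolysis and 0.115 for NRF2 targets, and without control replicate 3 it was 0.115 for basal and 0.147 for stem cell genes. Without anti-AL078604.2 replicate 2 it was 0.0846 for basal and 0.112 for stem cell genes. Without anti-AL078604.2 replicate 3 it was 0.49 for DNA replication, 0.174 for glycolysis, 0.194 for NRF2 targets, 0.0874 for basal and 0.0512 for stem cell genes.

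**Figure D3:**
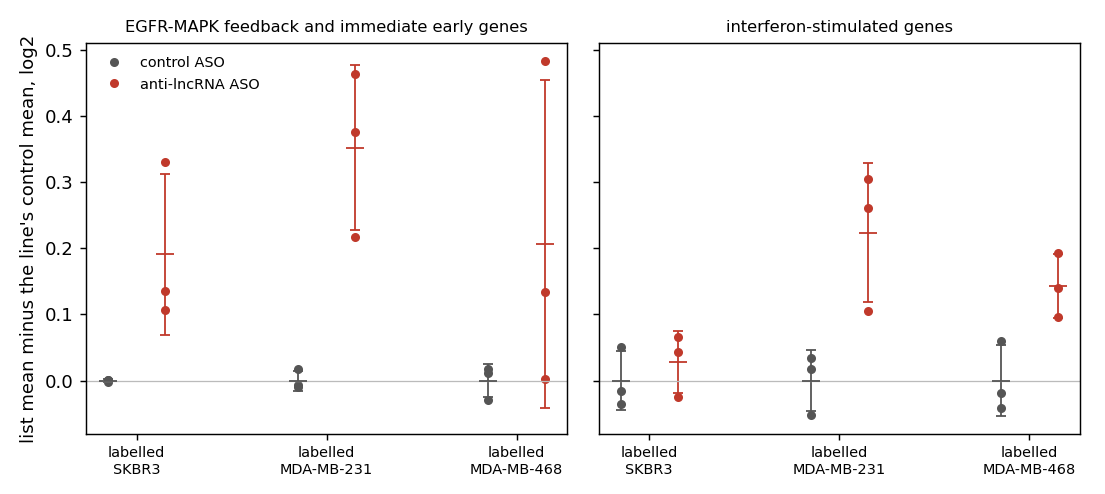
Mean log2 value of the immediate early and MAPK feedback genes (left) and interferon-stimulated genes (right) on each array, minus the mean of the labelled line's control arrays (vertical axis), with points for single arrays, horizontal bars for group means and error bars for SD (n = 3). The immediate early mean was 0.19 higher after the ASO in the arrays labelled SKBR3, 0.35 in those labelled MDA-MB-231 and 0.21 in those labelled MDA-MB-468.

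The remaining 13 lists were called in none of the 3 labelled lines. Their smallest camera adjusted p over the lines was 0.0555 for cytosolic ribosomal proteins, 0.135 for both heat shock response and luminal genes, 0.14 for both metallothioneins and RNA processing genes, and 0.286 for the unfolded protein response. It was 0.315 for the ERBB2 amplicon, 0.393 for p53 target genes, 0.427 for extracellular matrix and integrins, 0.489 for epithelial genes and 0.533 for G2/M and mitosis. It was 0.681 for MHC class I antigen presentation and 0.705 for oxidative phosphorylation. The median, mean and camera direction differed in sign for 3, 6 and 5 lists in the arrays labelled SKBR3, MDA-MB-231 and MDA-MB-468, with the smallest adjusted p among these 0.676, 0.538 and 0.961, and for 0 of the lists called.

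The same ASO was compared between the arrays labelled MDA-MB-231 and MDA-MB-468. CMTM3 was called in both, which was the 1 shared rise against 0.00194 expected for independent lists (two-sided Fisher's exact p = 0.00194), and there were 0 shared falls. All 26 named calls of the arrays labelled MDA-MB-231 had the same sign in those labelled MDA-MB-468, as did 45 of all 51, and 35 of the 51 also had an unadjusted p under 0.05 there. Across genes, which are not independent replicates, the fold changes correlated with r = 0.326 and rho = 0.28. Without the filter on dim features r was 0.19, and with the stricter filter it was 0.491. Of 758 features with an unadjusted p under 0.05 in both, 734 (96.8%) had the same direction. These lines shared no control arrays, but the fit gave them a common estimate of each feature's spread. Their lists of calls are therefore not independent, and the Fisher p, which rests on 1 gene, is only a description. The arrays labelled SKBR3, which received another ASO, correlated with those labelled MDA-MB-231 with r = 0.14 and with those labelled MDA-MB-468 with r = 0.054. The share with the same direction was 237 of 303 features (78.2%) for SKBR3 with MDA-MB-231. For SKBR3 with MDA-MB-468 it was 175 of 293 (59.7%). Whether the values for the pairs with SKBR3 go beyond chance was not tested. For the lines given the same ASO, other splits of the arrays gave a median absolute r of 0.099 and at most 0.335. With 0 calls in the arrays labelled SKBR3, an overlap of calls with them could not be tested.

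The chemokine gene CCL2 had the largest difference among the genes named for the contrast between these lines (1.72 ± 0.401 log2 higher response in the arrays labelled MDA-MB-231), which did not pass. PEX6, a peroxisome biogenesis gene (0.45), HMGN2 (0.53), the prostaglandin synthase gene PTGES (0.68) and MSH5 (0.42) also had higher values, and the actin-binding gene CALD1 (-0.36), KANK4 (-0.57), FAM241A (-0.49), ZNF14 (-0.56) and OXGR1 (-0.58) lower ones. limma called 0 features for the difference (smallest adjusted p = 0.998), and 1243 had an unadjusted p under 0.05. An effect that passed in the arrays labelled MDA-MB-231 alone was thus not shown to differ from that in the arrays labelled MDA-MB-468.

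Averaged over both labelled lines, a comparison added after the data had been seen, the anti-AL078604.2 ASO changed 478 features in limma's test, 210 higher and 268 lower. TFPI2 rose 4.32-fold (2.11 ± 0.256 log2, adjusted p = 0.00225), and CMTM3 (0.71, 0.00102), EDN1 (0.92, 0.00454), DUSP1 (0.88, 0.00466) and CPA4 (0.84, 0.00466) also rose. Further rises were those of the oxidized lipoprotein receptor gene OLR1 (0.94), the cornified envelope gene SCEL (0.77), the annexin gene ANXA1 (0.77), the tetraspanin gene TSPAN2 (0.77) and IFIT2 (0.72). Among falls were WDR7 (-1.07, 0.00689), IPO9 (-1.02, 0.00453), the zinc finger gene ZKSCAN1 (-1.02, 0.00753), MIX23 (-1.01), the polarity gene PARD3B (-0.92), WDR4 (-0.87, 0.00453), the Elongator subunit gene ELP4 (-0.85), the nuclear receptor corepressor gene LCOR (-0.81), THRSP (-0.74) and RGP1 (-0.74). Of the calls, 264 had a symbol. TFPI2, CMTM3, EDN1, DUSP1, CPA4, SCEL, WDR7, IPO9, ZKSCAN1, PARD3B and WDR4 passed in each of 12 omissions of 1 array.

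The averaged count moved by more than 1.5-fold with each array left out. In the arrays labelled MDA-MB-231 it was 227, 170 and 102 without control replicate 1, 2 and 3 in turn, and 1431, 91 and 111 without anti-AL078604.2 replicate 1, 2 and 3. In those labelled MDA-MB-468 it was 128, 141 and 164 without control replicate 1, 2 and 3, and 147, 198 and 969 without anti-AL078604.2 replicate 1, 2 and 3. OLR1, ANXA1, TSPAN2, IFIT2, MIX23, ELP4, LCOR, THRSP and RGP1 each lost their call in at least 1 omission, with an adjusted p of up to 0.119 for THRSP.

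Averaged over both labelled lines, immediate early and MAPK feedback genes rose by a median of 0.28 log2 over 27 genes (camera adjusted p = 2.61e-10, and adjusted p = 0.274 with an estimated correlation). Over all genes 4 members passed, DUSP1, JUN, EGR1 and the feedback inhibitor gene SPRY4, and when adjusted over the list alone 16 rose and 1 fell. Interferon-stimulated genes rose by a median of 0.13 over 24 genes (9.67e-05, and adjusted p = 0.135 with an estimated correlation), with 4 passing over all genes (IFIT2, HERC5, IFIT3 and SAMD9) and 5 when adjusted over the list alone. TGF-beta targets rose (0.024, and adjusted p = 0.135 with an estimated correlation), with SMAD6 (0.38) and the repressor gene TGIF1 (0.28) passing on both counts. Nucleic acid sensing genes (0.019, and adjusted p = 0.135 with an estimated correlation) and NF-kB inflammatory genes (0.0196, and adjusted p = 0.425 with an estimated correlation) rose, each with 0 members passing over all genes and 3 when adjusted over the list alone. Basal epithelial genes fell by a median of -0.11 (0.0155, and adjusted p = 0.298 with an estimated correlation), with KRT5 (-0.29) passing over all genes and 2 members when adjusted over the list alone. Several members lost their call in most of the 12 omissions of 1 array, IFIT2, IFIT3, TGIF1 and KRT5 in 9 and HERC5, SAMD9 and SPRY4 in 10, with an adjusted p of up to 0.129 for SAMD9. The NF-kB call was lost without anti-AL078604.2 replicate 2 of the arrays labelled MDA-MB-231 (0.0745), or control replicate 1 (0.0908) or anti-AL078604.2 replicate 1 (0.0568) of those labelled MDA-MB-468. The TGF-beta call was lost without anti-AL078604.2 replicate 1 of the arrays labelled MDA-MB-231 (0.0704), or control replicate 2 (0.0511) or anti-AL078604.2 replicate 1 (0.05004) of those labelled MDA-MB-468.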

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

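The averaged comparison, the exact permutation of list means, the tests of the authors' processing, of gene names by the epithelial list, of other cells than labelled, of a length trend between arrays and of single arrays were chosen only after the result was seen, as was the bound on the SD for single arrays, and the condition of the length test between arrays was reworded once its p was known.

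The response to the anti-AL078604.2 ASO differed between the arrays labelled MDA-MB-231 and those labelled MDA-MB-468 for 6 lists, by camera on the difference itself. DNA replication and G1/S genes (adjusted p = 2.77e-05), immediate early and MAPK feedback genes (0.0133), NF-kB inflammatory genes (0.0238) and NRF2 targets (0.0438) responded more positively in the arrays labelled MDA-MB-231, and cholesterol and fatty acid synthesis genes (0.0133) and glycolysis and hypoxia genes (0.0377) less. With an estimated correlation their adjusted p ran from 0.613 to 0.647. No single gene passed for this difference. The DNA replication list alone kept its call in all 12 omissions of 1 array, with an adjusted p of at most 0.00167. The NF-kB call was lost in 6 omissions (up to 0.178), cholesterol in 4 (up to 0.173), glycolysis in 6 (up to 0.47), NRF2 in 7 (up to 0.172) and immediate early genes in 3 (up to 0.411).

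The first pattern is that the ERBB2 amplicon and epithelial lists stood at similar levels in the control arrays of the 3 labelled lines. Processing that set each feature's mean fully equal across lines is argued against. Control means differed between lines by at least 2.38 times what replicate spread gives, where a ratio of at most 1.5 was called for. Processing that drew the lines only partly together could also leave a ratio above 1.5, so this test cannot decide on it. Gene names attached to the wrong features were tested on ribosomal protein genes, whose lowest median percentile of 86.9 met neither bound set beforehand, and then on the epithelial list, whose lowest median percentile of 94.5, against at most 80.4 for the 95th percentile of random lists, argues against names attached at random, though not against single wrong names. Also open is that the arrays labelled SKBR3 may hold other cells than labelled, since the ERBB2 amplicon was higher there by only 0.0356 log2. The same was not settled for the other lines. AXL was highest in the arrays labelled MDA-MB-231 (1.09, percentile 83.2), which ran with their label. It was nearly as high in percentile in those labelled SKBR3 (0.67, percentile 80.85), and both differences include the low value of those labelled MDA-MB-468 (-1.76). ZEB1 in the arrays labelled MDA-MB-231 was higher only relative to the other lines (0.39), and stood at the 45.9 percentile of all features. A mesenchymal median of -0.16, VIM at -0.29 and EPCAM at the 99.2 percentile ran against that label. Low RB1 (-1.60) in the arrays labelled MDA-MB-468 and the highest luminal list (0.30) in those labelled SKBR3 ran with the labels.

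The second pattern is a median below 0 after ASO treatment for protein-coding genes with spans over 100 kb, -0.04 log2 (interquartile range -0.14 to 0.03) in the arrays labelled SKBR3 and -0.07 (-0.18 to 0.03) in those labelled MDA-MB-231. The arrays labelled MDA-MB-468 showed almost no trend, with -0.02 (-0.13 to 0.08) for long genes, -0.01 for genes under 10 kb and a rank correlation with length of -0.0116, against -0.142 and -0.201 in the other lines. A length trend between single arrays unrelated to the ASO cannot be told apart from an ASO effect. The exact permutation p over 3 lines was 0.106, and the largest range within a group exceeded the difference between group means in the arrays labelled SKBR3 (0.351 against -0.126) and MDA-MB-468 (0.662 against -0.037) but not in those labelled MDA-MB-231 (0.181 against -0.27). A response shared by both lines given the anti-AL078604.2 ASO was not settled either, since their fold changes over long genes correlated by 0.313 more than either did with the arrays labelled SKBR3, but they also correlated more over all features (0.326 against 0.14 and 0.054).

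The third pattern is a higher mean of immediate early and MAPK feedback genes after the ASO. It was 0.19, 0.35 and 0.21 log2 higher in the arrays labelled SKBR3, MDA-MB-231 and MDA-MB-468. The exact permutation tested the 3 lines together, not each line (mean difference of 0.25 log2, p = 0.00075 over 8000 assignments). By fry, the adjusted p in the same order was 0.498, 0.0309 and 0.286. The gene length trend is argued against as the whole cause, since with it removed the mean difference was 0.24 and the exact p 0.00025, the smallest the permutation can give. A single array is argued against in the arrays labelled SKBR3 and MDA-MB-231, where the mean difference without any 1 array was at least 0.121 log2 and above the SD of the treated arrays that remained. In those labelled MDA-MB-468 a single array stays open, since without anti-AL078604.2 replicate 1 the difference dropped from 0.21 to 0.0684, within that SD (0.0925), and the camera call was lost (adjusted p = 0.404). A response common to these ASOs and an effect of each target may both underlie it, and this design, with 1 control ASO per line, did not test between them.

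Other splits of the arrays were fitted in the same way. For each single line there are 10 splits, too few for a share under 0.05. In the arrays labelled SKBR3 the real count was 0 and the highest other 1. In those labelled MDA-MB-231 the real count was 51 and the highest other 0 (1 of 10), and in those labelled MDA-MB-468 it was 2 and the highest other 0 (1 of 10). For the difference between lines the real count was 0, which every one of 100 drawn splits reaches, so the splits say nothing about chance there. The highest other was 185, from the split that gave the highest other of the averaged comparison, with the labels of 1 line reversed. For the averaged comparison, only the real split of the 100 reached its count of 478, and the highest other was 185. This argues against chance at a share under 0.05, for a comparison chosen after the data had been seen. For the correlation of fold changes, 2 of 100 splits, the real one included, had an absolute value as large as the real 0.326. The share was under 0.05, but chance is not excluded, since another split gave a larger absolute value (0.335). Splits that differ only by reversed labels in 1 line give the same absolute value, so the 100 splits are not independent.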

How the results depend on the processing

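The averaged comparison, its list tests, the exact permutation and the removal of the length trend were chosen after seeing the data. The counts of calls depended strongly on the settings, and except as said the cause was not tested. In the order of the arrays labelled SKBR3, MDA-MB-231, MDA-MB-468 and the average, array weights gave 0, 2413, 5199 and 5837 calls, with 309 for the difference between lines; the weights ran from 0.377 to 9.62. No filter gave 1, 28, 2 and 263, the stricter filter 0, 99, 1 and 730, fitting only the arrays of a comparison 0, 3, 0 and 259, and the robust fit without trend 0, 26, 3 and 311. With 1 feature per symbol, which tests fewer features, the counts were 0, 113, 25 and 582. With adjusted p and 2-fold they were 0, 20, 0 and 19, and with unadjusted p and 2-fold 94, 84, 24 and 25, with 72 for the difference. Quantile normalization (0, 50, 2 and 470) and centring (0, 42, 2 and 406) stayed within 1.5-fold. Leaving out 1 array gave 0 to 231, 0 to 532, 0 to 12 and 91 to 1431 calls, and 0 to 0 for the difference. The correlation of fold changes between the lines given the anti-AL078604.2 ASO was 0.19 without a filter and 0.491 with the stricter one. The call shared by both lines became 0 with adjusted p and 2-fold and with the replicate block. With the replicate number as a block, the counts were 0, 0, 0 and 113, and 3 lists in MDA-MB-468. Same-numbered arrays deviated together with correlations of -0.02, 0.10 and 0.04, -0.04, -0.02 and -0.06, and -0.12, 0.05 and 0.02 in the 3 lines. These small values gave no sign of pairing by number. Differently numbered arrays were not compared, so pairing is not excluded. An estimated correlation gave 0 lists in each comparison, and fry gave 0, 7, 0 and 4, with 0 for the difference. No filter left 1 list in SKBR3. Leaving out 1 array gave 2 to 4, 7 to 10, 2 to 5 and 4 to 8 lists, and 2 to 9 for the difference. PGK1 in the difference turned from -0.21 to 0.0167 log2 under array weights. Of the settings of single genes in MDA-MB-231, 707 kept side and direction, 192 lost and 44 gained a call, and for the average 788, 143 and 23. The 15 settings planned for LINC01269 and AL078604.2 themselves were not run. Signal over background was not given, so what dim features limit was not measured.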

Other observations

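The exact permutation of list means, the test of the length trend on the correlation and the test of neighbouring genes were chosen only after the result was seen.

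Over all 3 labelled lines together, exact two-sided permutation of per-array list means within lines (8000 assignments, 28 lists) gave 9 lists with an adjusted p under 0.05, of which heat shock, p53 and RNA processing genes were called in no single line. Heat shock genes had a mean difference of 0.06 log2 (adjusted p = 0.014) and were above the control mean on all 3 treated arrays of each labelled line. p53 target genes (0.06) and RNA processing genes (0.04) both had adjusted p = 0.0389, as did YAP and TEAD targets (0.11) and, lower, basal epithelial genes (-0.11). Nucleic acid sensing genes (0.10) and immediate early genes (0.25) had adjusted p = 0.0105, interferon-stimulated genes (0.13) 0.014 and TGF-beta targets (0.09) 0.0168. Over both lines given the anti-AL078604.2 ASO (400 assignments), the smallest adjusted p was 0.07, so 0 lists passed, while 10 of the lists had an unadjusted exact p under 0.05. The smallest exact p that 400 assignments can give is 0.005. Interferon-stimulated and nucleic acid sensing genes had that p and still had an adjusted p of 0.07. With 28 lists this permutation could therefore hardly call a list, and the absence of calls says little.

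Genes that set the labelled lines apart in control arrays, on a quantile-normalized scale, were few. The breast and sweat gland gene MUCL1 (3.44 log2) and the proteoglycan gene SRGN (2.31) were higher in the arrays labelled MDA-MB-231 than in the others, and MIR130B (3.65) and SERF2 (3.50) in those labelled SKBR3. In those labelled MDA-MB-468, the ceruloplasmin gene CP (2.46) and the growth factor binding gene IGFBP3 (2.10) were higher. At least 4-fold differences were found for 43 of 29855 features between the arrays labelled SKBR3 and MDA-MB-231, 54 between those labelled SKBR3 and MDA-MB-468 and 14 between those labelled MDA-MB-231 and MDA-MB-468. The control means correlated with r = 0.975, 0.971 and 0.980 in the same order.

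A gene length trend was tested as a candidate explanation of the correlation of fold changes between both lines given the anti-AL078604.2 ASO. Over 9727 protein-coding genes r was 0.495, and 0.49 with the trend removed, which argues against the trend as its cause.

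Neighbouring genes might change together after the anti-AL078604.2 ASO. Among the averaged calls, 4 pairs of adjacent genes had the same direction, INTS7 with DTL and SEL1L3 with SMIM20 lower, and IFIT2 with IFIT3 and HOXC13 with HOXC12 higher. Random gene sets of the same size gave a median of 3 and a 95th percentile of 6 (permutation p = 0.364), so the count was not beyond chance.

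Loss of LINC01269 might alter genes beside it. Its 10 nearest named genes, with TTC9 (-0.32 log2, limma adjusted p = 0.432) the furthest from 0, had a median absolute change of 0.04997 log2 in the arrays labelled SKBR3, against a 95th percentile of 0.159 for runs of 10 neighbouring genes. No local change was detectable by this test.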
